A study of Mus musculus with 2 samples.

How the data were processed

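Accessible chromatin was measured by DNase-seq, in which nuclei are cut with DNase I and the cut ends are sequenced, so that open DNA yields many cuts. The samples were thymus tissue of 2 female B6CASTF1/J mice aged 14 days, the first-generation cross of C57BL/6J and CAST/EiJ. Per the labels they are biological replicates 1 and 2 of 1 group, with different animal numbers and a shared donor identifier. They were taken here as 2 separate animals. The series has no treated, mutant or control group.

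Per the listing of files that the authors deposited with each sample, peaks, a track of false discovery rates and footprints were each made from that sample's own alignments to mm10, so replicates were not pooled. How reads of the CAST alleles were mapped to mm10, the aligner, the peak caller, the footprint caller and their settings are not given in the sources used here. The deposited signal of a peak, called its strength below, is the authors' own value. All strengths of a replicate were whole multiples of 1 step (0.00519 in replicate 1 and 0.00576 in replicate 2), with a tolerance of 0.05 steps. That is the pattern of counts divided by 1 factor per sample, and the rule behind the factor is not given in the sources used here. Strengths were therefore used to rank and describe peaks within a replicate, and between replicates in correlations of ranks or of log2 values and as differences between classes of peaks on the log2 scale, from which a common factor cancels. The factor does not cancel from the mean of both deposited strengths, which was used only to order promoters and shared peaks, and in which replicate 1 weighs more because its strengths are mostly larger (mean over its peaks 2.16, against 1.34 in replicate 2). The step of replicate 2 was 1.11 times that of replicate 1. The read depth itself is not given in the sources used here. Strengths are given below without counting intervals. The deposited p-value column of the track is a false discovery rate (q-value) per run of bases, and the authors' files list only runs under 0.05. The corresponding column of the footprint files is 0.01 throughout and was not used as a measurement.

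The authors deposited 2 peak lists per replicate. Every peak of the longer list held a base with a false discovery rate under 0.05 in the same replicate's track, and every peak of the shorter list held a base at 0.001 or less. The longer list was used throughout, and the shorter list served as the stricter alternative. Chromosomes 1 to 19, X and Y were kept. Annotation came from the GENCODE M21 basic set and sequence from the GRCm38.p6 assembly, whose primary chromosomes are those of mm10; no peak ended beyond its chromosome. Coordinates are 1-based mm10 positions.

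Overlap of the replicates was the share of peaks sharing at least 1 bp with a peak of the other replicate, with 95% Wilson intervals. It was set against 100 circular shifts of a peak list along each chromosome. Strengths were compared over peaks that overlapped one to one. A peak was TSS-proximal when its midpoint lay within 500 bp of the transcription start site (TSS) of a protein-coding gene; the other peaks were assigned to exons, introns or the space between genes. A promoter was open when a peak lay within 500 bp of any annotated TSS of the gene in both replicates.

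Before the data were examined, 12 gene lists with 214 genes and 21 consensus motifs were fixed, as were the tests and most of the alternatives. The background was 21701 protein-coding genes on chromosomes 1 to 19 and X, after 27 duplicated symbols were left out. Open promoters of each list were compared with all other genes by Fisher's exact test, two-sided. Distal peaks were those over 500 bp from any TSS. For each list, the median number per 100 kb of gene body and 25 kb to each side was compared with 10000 random lists of the same size matched on gene span, in a two-sided permutation test. Random genes were drawn from span classes and could recur within a random list where the class was large. Footprints with 5 bp added to each side were compared with equally wide windows of the same peaks outside footprints. Footprints outside peaks, or for which no such window was found, were left out. Distal peaks were compared with windows of the same width 2 kb away and outside peaks. Both motif comparisons used Fisher's exact test in each replicate, and a call needed the same direction and an adjusted p under 0.05 in both. All families were adjusted by the Benjamini-Hochberg method. Genes, peaks and footprints are not replicates, and neighbouring genes share distal peaks, so these p-values describe the 2 libraries and not a population of animals. With 1 animal per library no test between animals was made, and intervals of shares cover counting error only. Bootstrap intervals came from 1000 resamplings of genes or peaks within the 2 libraries, so they do not measure the spread between animals.

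Genes named in the text followed a rule fixed in advance. It took the 12 strongest promoters of the thymocyte and T cell list by mean strength, any member of that list without a promoter peak, and the 2 strongest promoters of each other list. It added the 10 genes with the most distal peaks, the genes nearest to the 5 strongest shared peaks, and those nearest to the 3 strongest unshared peaks of each replicate. A gene sharing most of its distal peaks with a gene already taken was left out of those 10. Other genes named below were chosen after their values were seen. Some genes that the rule takes are not reported here.

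Alternatives comprised the shorter peak list, reciprocal overlap of at least 50%, the stronger 50% of each list, equal numbers of peaks, promoter windows of 1000 and 2000 bp, a promoter peak in either replicate or at the outermost TSS only, and flanks of 0 and 100 kb. They also comprised random lists matched on the CpG ratio around the outermost TSS, sequences shuffled with their dinucleotides kept, and leaving out each replicate. Copies of a peak in the genome were counted as exact matches on either strand of 5 evenly spaced words of 32 bases.

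The steps were tested on simulated data. In the simulated overlap of 97051 peaks, 59.9% were kept, each moved by a small random distance, and 60.5% were recovered. For promoters, in simulations on 21701 genes, 95.5% of lists planted with 95% open promoters and 99% of lists planted with 10% were called, as were 2.06% of unchanged lists. For distal peaks, a list planted at 3-fold density was called, and so was 1 of 11 unchanged lists. For motifs, a site planted in 4.95% of 19227 sequences was recovered in 4.89% above the control, and none of the 21 motifs was called without planting. Both sides of that comparison were shuffles of the same sequences, so it gives no rate of false calls against real windows. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and bedtools 2.31.1. Plots were drawn with matplotlib 3.10.9.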

Results

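DNase-seq peaks, footprints and false discovery rates were available for the thymus of 2 female B6CASTF1/J mice aged 14 days. The thymus is the organ in which T cells mature, and most of its cells at this age are thymocytes. The design holds 1 group, so it yields a description of open chromatin in this tissue and a comparison of the 2 animals. The read depth is unknown from the deposited tables.

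Replicate 1 had 97051 peaks and replicate 2 had 108010. They covered 18.6 Mb and 24.2 Mb, or 0.701% and 0.914% of the sequenced genome. Autosomes held 39.4 and 43.8 peaks per Mb and the X chromosome 16.02 and 18.2, whereas the Y chromosome held 0.670 and 0.477. Among autosomes, chromosome 11 was the densest in both replicates, with 63.9 and 68.7 peaks per Mb. Peaks had a median width of 188 and 200 bp. Wide peaks over 400 bp made up 2.78% of peaks in replicate 1 and 10.1% in replicate 2. The strongest 10% of peaks held 54.4% of the summed strength in replicate 1 and 44.3% in replicate 2. The false discovery rate track listed 32.1 Mb and 43.4 Mb under 0.05, of which 68.5% and 67.1% lay at 0.001 or less. The stricter lists held 64927 and 72884 peaks.

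Open chromatin was concentrated at gene starts. TSS-proximal peaks made up 18.2% ± 1.96 (SD, n = 2) of peaks, 17.0 ± 1.84-fold their share of the genome. Introns held 42.9% ± 1.68, exons 7.76% ± 0.423 and the space between genes 31.1% ± 0.704. TSS-proximal peaks were also the strongest class, with a median strength of 2.66 in replicate 1 against 0.712 in introns and 0.649 between genes. In replicate 2 the corresponding medians were 2.15, 0.576 and 0.553. Among the stronger 50% of peaks the TSS-proximal share was 27.8%, or 27.9 and 24.2-fold its share of the genome in replicates 1 and 2. With a window of 2000 bp it was 31.7% but 8.38 and 8.05-fold, and with TSSs of all genes it was 21.4% and 10.02 and 8.71-fold.

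The next question was how far the 2 animals had the same open regions. Of the replicate 1 peaks, 75.2% (95% Wilson interval 74.96 to 75.51%) overlapped a replicate 2 peak, and 66.4% (66.09 to 66.65%) of the replicate 2 peaks overlapped a replicate 1 peak. The highest values in 100 shifts of the lists were 1.93% and 1.73%. The Jaccard index of covered bases was 0.436, against 0.00471 in the highest shift. Promoter regions were shared most often. Among TSS-proximal peaks 85.1% of replicate 1 and 86.7% of replicate 2 were shared, against 71.3% and 61.0% between genes. Sharing rose with strength, from 25.1% and 13.0% in the weakest 10% of peaks to 98.9% and 99.3% in the strongest 10%. Over the 64454 peaks that paired one to one, Spearman's rho of strength across peaks was 0.827 and Pearson's r of log2 strength was 0.852; peaks are not independent replicates. A reciprocal overlap of at least 50% lowered the shared percentages to 56.8% and 51.1%.

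**Figure D1:**
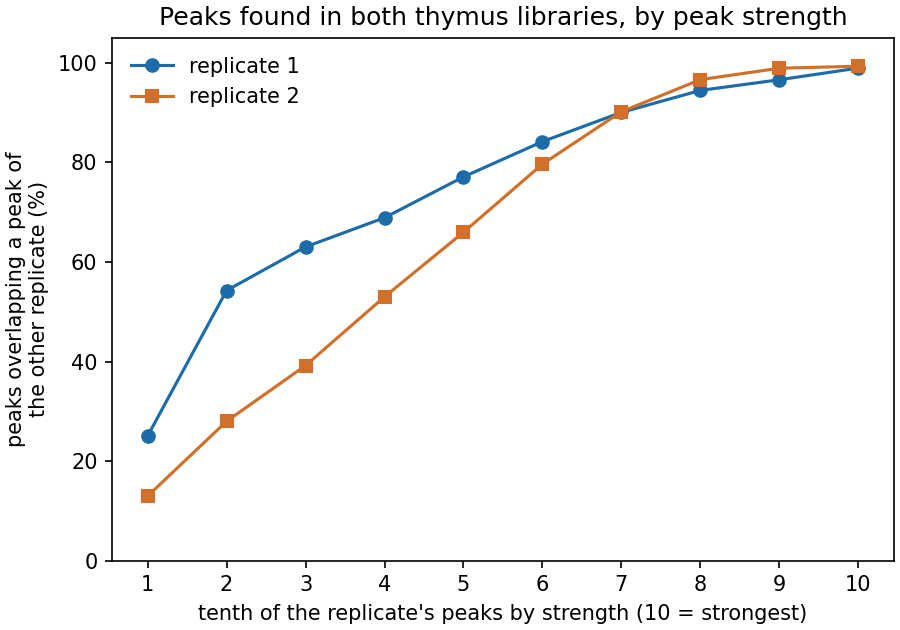
The share of each replicate's peaks that overlap a peak of the other replicate by at least 1 bp (y axis, percent) is plotted against the tenth of that replicate's peaks by strength (x axis, 10 the strongest), with circles for replicate 1 and squares for replicate 2. Both lines rise, from 25.1% and 13.0% to 98.9% and 99.3%.

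Peaks found in both replicates were ranked by the mean of their strengths as deposited, and none of the 5 strongest had a gene of the thymocyte and T cell list as its nearest TSS. The first by that mean, though the strongest in neither replicate, was at chromosome X 143482981 to 143483140, between genes, 35530 bp from the nearest protein-coding TSS (Pak3, a kinase of the cytoskeleton), with a strength of 55.3 in replicate 1 and 58.9 in replicate 2. A pair of peaks at chromosome X 169997981 to 169998240 and 169998261 to 169998420 lay in an intron of Mid1, with Gm21887 as the nearest TSS. Their strengths were 82.1 and 78.4 in replicate 1 and 24.2 and 22.9 in replicate 2. The peak at chromosome 17 39846781 to 39846920, in an intron of CT010467.1 with Esp38 as the nearest TSS, had 17.95 in replicate 1 and 81.2 in replicate 2. The last, at chromosome 17 6430001 to 6430180, 21 bp from the TSS of Dynlt1b, had 57.3 and 29.4. The median numbers of genome copies of the 32-base words of these peaks were, in the order given, 1, 8, 6, 2 and 3. Copies that the assembled chromosomes lack are not in these numbers, and no regions prone to artefacts were left out. The strongest peaks without an overlapping peak in the other replicate were all near gene starts. In replicate 1 they lay near Mbd3, a member of the nucleosome remodelling and deacetylase complex, Banp and Rap2a, and in replicate 2 near Camta1, Exosc8 and Mbd3. The Mbd3 peaks, at chromosome 10 80399621 to 80399900 in replicate 1 and 80399361 to 80399560 in replicate 2, were neighbouring calls. All 6 held at least 1 base listed under a false discovery rate of 0.05 in the other replicate.

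Promoters of thymocyte and T cell genes were open in both animals. All 40 genes of that list had a peak at 1 or more annotated TSSs in both replicates, against 58.5% of other protein-coding genes (Fisher's exact test, adjusted p = 8.3e-09, over 12 lists), and 39 had one at the outermost TSS. Among the 12 strongest was Lat, a scaffold of T cell receptor signalling, with a promoter strength of 20.8 in replicate 1 and 4.99 in replicate 2. Ets1 had 14.9 and 9.54, the receptor subunit gene Cd3g with 18.5 and 4.93, and the kinase gene Lck with 17.3 and 4.99. Also among the 12 were the chromatin organizer gene Satb1, the coreceptor genes Cd8b1 and Cd8a, the recombinase genes Rag1 and Rag2, the lineage factor gene Bcl11b and Themis. The strengths of these 7 ranged from 9.21 (Themis) to 15.2 (Satb1) in replicate 1 and from 3.25 (Rag1) to 5.96 (Satb1) in replicate 2. The Rag1 promoter peak lay at chromosome 2 101649501 to 101649720 in replicate 1, at the TSS of the minus-strand gene, and the Lck peak at chromosome 4 129558341 to 129558540.

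Genes used by all or by dividing cells were also open. By the same exact test, all 18 cell cycle genes (adjusted p = 4.3e-04) and all 15 ubiquitous genes (adjusted p = 8.9e-04) had a promoter peak in both replicates. The strongest were the replication helicase genes Mcm4, with 24.4 in replicate 1 and 7.92 in replicate 2, and Mcm5, with 19.2 and 11.2, and the ubiquitous genes Hsp90ab1, with 32.7 and 13.0, and Rplp0, with 22.3 and 13.8. Against random lists with a like promoter CpG ratio, the thymocyte and T cell list passed the permutation test (100% against a random median of 47.5%, adjusted p = 0.0024, the smallest that 10000 draws can give here). The cell cycle and ubiquitous lists could not pass upward in that permutation test (adjusted p = 0.35 for each), since the 97.5% quantile of their random lists was also 100%, so it says nothing about them.

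Promoters of 4 lists of other lineages were open less often than the background of 58.6%. None of the 16 hepatocyte genes had a promoter peak in both replicates (exact test, adjusted p = 4.4e-06), and neither replicate alone had any. By the exact test striated muscle had 1 of 13 (Ryr2, adjusted p = 6.1e-04), the erythroid list 1 of 12 (adjusted p = 9.0e-04) and the myeloid and dendritic list 4 of 18 (adjusted p = 0.0048), Itgam among them. The neuron list, with 7 of 14, did not pass (exact test, adjusted p = 0.59); it was led by Grin1 and Syn1 at 1.69 and 1.86 in replicate 1. All 4 lists stayed below the random median of CpG-matched lists. The shares were 7.69% against 38.5% for striated muscle, 0% against 18.75% for hepatocyte, 8.33% against 16.7% for erythroid and 22.2% against 27.8% for myeloid genes. Of the 4 lists, only striated muscle passed that permutation test (adjusted p = 0.049). The hepatocyte (0.18, at the lowest possible share), erythroid (0.49) and myeloid (0.99) lists had adjusted p-values above the threshold.

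Lists of further cell types of the thymus did not pass the exact test. Promoters were open in both replicates for 9 of 19 thymic epithelial genes (exact test, adjusted p = 0.43), led by the chemokine gene Ccl25 at 9.67 and 8.28 and by Ly75, and for 6 of 15 B cell genes (adjusted p = 0.25), led by Ebf1 at 4.52 and 4.31 and Cr2. The effector, regulatory and innate lymphocyte list had 9 of 18 (exact test, adjusted p = 0.52), led by Id2 at 14.3 and 5.60 and the perforin gene Prf1. Endothelium and mesenchyme had 5 of 15 (exact test, adjusted p = 0.096), led by Pecam1 at 6.64 and 2.50 and Pdgfra. Set against CpG-matched lists, B cell genes (40% against a random median of 20%) and effector lymphocyte genes (50% against 38.9%) lay above it. Thymic epithelial genes (47.4% against 52.6%) and endothelial and mesenchymal genes (33.3% against 40%) lay below it. None of these lists passed that permutation test (adjusted p from 0.35 to 0.99).

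Away from promoters, distal peaks clustered around thymocyte and T cell genes. That list had a median of 18.8 distal peaks per 100 kb, against 4.17 in random lists matched on gene span (permutation test, adjusted p = 0.0024, the smallest that 10000 draws can give here). The medians were 17.2 in replicate 1 and 19.8 in replicate 2, and 39 of the 40 genes lay above the random median, with Themis, at 3.01, the exception. The coreceptor genes Cd8b1 and Cd8a had 83.5 and 48.4 distal peaks per 100 kb as means of the replicates, Rag1 26.1, Lck 25.9 and Bcl11b 18.2. Neighbours in the list, such as Cd8a and Cd8b1 or Rag1 and Rag2, share part of their flanks and so part of these peaks.

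No other list passed the distal test. The ubiquitous list had 9.76 distal peaks per 100 kb (permutation test, adjusted p = 0.056) and the B cell list 8.01 (adjusted p = 0.10). In the permutation test the ubiquitous list passed with either replicate alone, the B cell list with replicate 2 alone (adjusted p = 0.026), and the myeloid list with 100 kb flanks (adjusted p = 0.014). The effector lymphocyte list had 6.36, the thymic epithelial list 6.29, the myeloid list 5.35, the cell cycle list 4.72, the endothelial and mesenchymal list 3.46, hepatocyte genes 2.98, striated muscle genes 2.83, erythroid genes 2.44 and neuron genes 1.95 (permutation test, adjusted p from 0.25 to 0.97). By total number, distal peaks were most numerous at 2 very long gene models, Gm20388 (446 ± 36.8, SD, n = 2, over a span of 4434882 bp) and Fgfr2 (123.5 ± 19.1). Gm20696, Tbc1d22a, Wwox, Gm37240, Mad1l1, Smyd1, Bcor and Clec16a followed, with means from 73.5 down to 54. Genes sharing most of their distal peaks with a gene already taken were left out, among them Cd8b1, with a mean of 54. Smyd1, a muscle methyltransferase gene, neighbours Cd8b1 and has the same promoter peak.

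**Figure D2:**
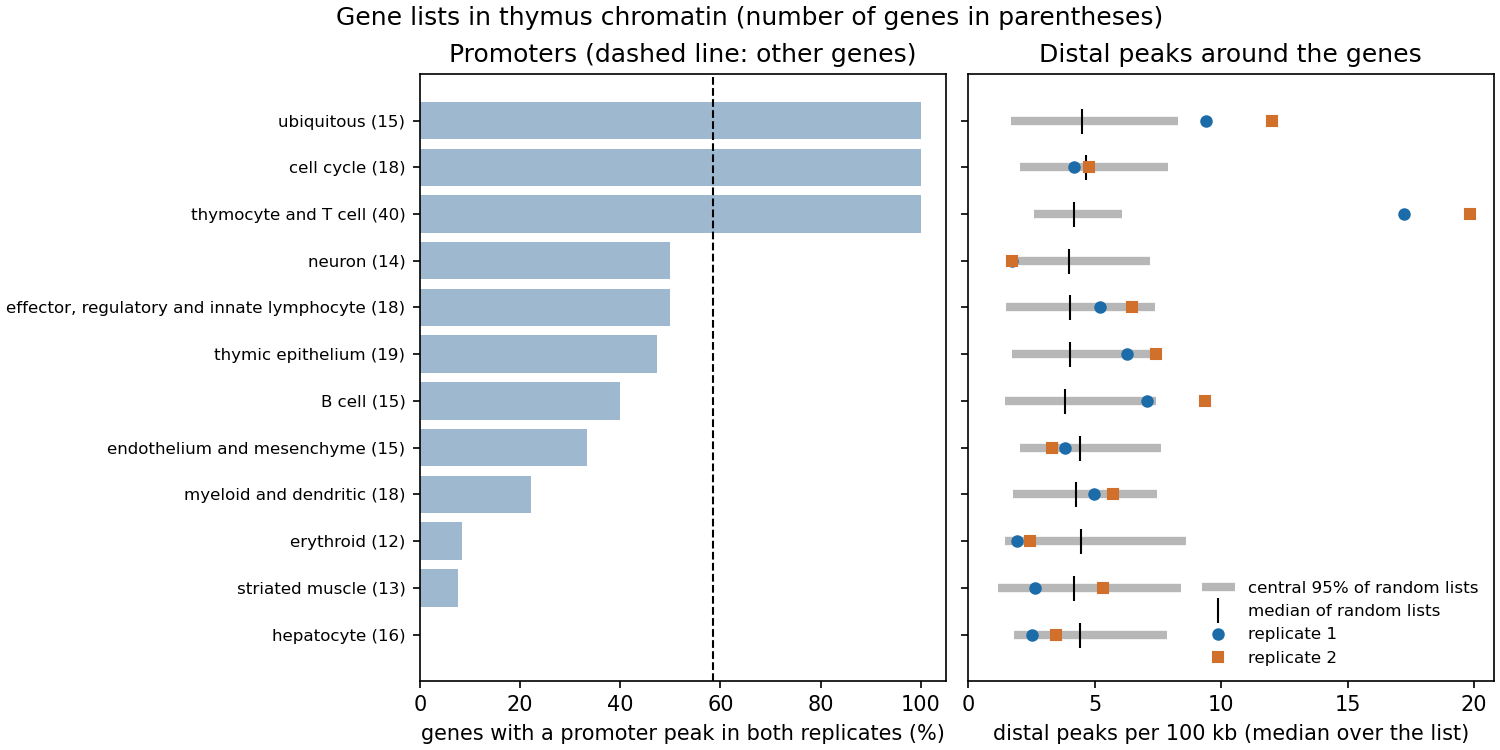
Left, bars give the percent of each list's genes with a promoter peak in both replicates, and the dashed line gives the value of other genes (58.6%); right, circles and squares give the median distal peaks per 100 kb in replicates 1 and 2, beside the median and central 95% of 10000 random lists. The thymocyte and T cell list, at 17.2 and 19.8, stands apart from its random lists.

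Consensus sites of CTCF, which anchors chromatin loops, were the sites most enriched in distal peaks against nearby windows among those with control sites in both replicates. They occurred in 6.72% of distal peaks of replicate 1 and 7.71% of replicate 2, against 0.0670% and 0.0708% of windows 2 kb away (mean log2 odds ratio 6.80 ± 0.10, SD, n = 2). Of the 5 motifs whose factor family has a member in the thymocyte and T cell list, a grouping made after the values were seen, 3 were enriched and 2 depleted. The log2 odds ratio was 1.96 ± 0.31 for ETS, 1.24 ± 0.25 for RUNX and 0.38 ± 0.14 for TCF/LEF sites, but -0.36 ± 0.06 for GATA and -0.27 ± 0.25 for Ikaros sites. The CAGCTG E-box, taken for E2A and HEB, had 1.18 ± 0.30 and the CAGGTG E-box, taken for the muscle factor MYOD, 1.06 ± 0.30. Which factors bind either string was not tested. Against sequences shuffled with their dinucleotides kept, the E-box ratios were lower, at 0.44 ± 0.15 for E2A and HEB and 0.53 ± 0.18 for CAGGTG, and the others were 2.13 ± 0.33 for ETS, 1.69 ± 0.36 for RUNX and 0.54 ± 0.33 for TCF/LEF sites. REST sites were found in 65 and 111 distal peaks and in 2 and 0 control windows. NRF1 (2.49), SP/KLF (1.75), CRE (1.48), C/EBP (1.42), YY1 (0.97), IRF (0.94), NF-kB (0.70) and AP-1 (0.42) sites were also enriched. In all, 15 of the 21 motifs were enriched by Fisher's exact test in both replicates. C/EBP sites were found in 25 and 27 distal peaks and in 8 and 11 control windows. REST, C/EBP, HNF4, HNF1 and MEF2 had been fixed in advance to stand for other tissues, and whether that grouping holds was not tested. Of these, 2 were enriched against nearby windows, REST and C/EBP. Against shuffled sequences REST stayed enriched and C/EBP was depleted. Besides GATA and Ikaros, sites of NFY (-0.17), HNF4 (-0.43) and HNF1 (-1.89, 3 sites in each replicate) were depleted, and MEF2 sites passed in neither direction. Against the shuffled sequences CTCF had 5.94, REST 6.63, NRF1 3.66, SP/KLF 2.79, CRE 2.15, IRF 1.503, YY1 1.47, AP-1 0.18 and NFY -0.65, and the direction turned for GATA (0.17), NF-kB (-0.23), Ikaros (0.47), HNF1 (0.16), MEF2 (1.63) and C/EBP (-1.26).

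Footprints are short stretches within open chromatin that DNase I cuts less than their surroundings, as happens where a protein covers the DNA. Replicate 1 had 276400 and replicate 2 had 318156, with a median width of 10 and 9 bp, and 83.7% and 84.4% lay in the same replicate's peaks. The mean number per peak rose with strength, from 0.978 and 0.786 in the weakest 25% of peaks to 4.19 and 4.80 in the strongest 25%. Of the replicate 1 footprints 50.8% overlapped a replicate 2 footprint, and 45.5% the other way round. When replicate 2 footprints were moved by 20 to 60 bp, 26.5% of replicate 1 footprints still overlapped one. With a reciprocal overlap of at least 50% the mean shared percentage fell from 48.2% to 33.5%.

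Within peaks, CTCF sites were again more frequent in footprints than outside them. They lay in 3708 of the 215299 footprints compared in replicate 1 and 4453 of the 254275 compared in replicate 2, against 25 and 39 control windows (log2 odds ratio 7.03 ± 0.26, SD, n = 2). Against the same windows, sites of factors that bind CpG-rich promoters were enriched as well, with NRF1 at 5.76 ± 0.48, CRE at 3.76 ± 0.28 and SP/KLF at 3.36 ± 0.51. REST sites lay in 48 and 87 footprints and in 0 and 1 control windows. Of the same 5 motifs, TCF/LEF (0.96 ± 0.70), RUNX (0.71 ± 0.23) and ETS (0.50 ± 0.15) were enriched, GATA was depleted (-0.60 ± 0.01) and Ikaros sites, at 0.30 ± 0.28, passed in neither direction. The E-box of E2A and HEB stood at 0.18 ± 0.16. The order depended on the control. Against shuffled sequences ETS had 2.76 ± 0.32, RUNX 2.21 ± 0.49, TCF/LEF 1.42 ± 0.64 and the E-box 0.53 ± 0.20, beside 7.13 for CTCF, 4.27 for NRF1, 4.58 for CRE and 2.44 for SP/KLF. IRF (1.09), YY1 (0.81) and the CAGGTG E-box (0.15) were enriched too, with 2.74, 4.99 and 0.48 against shuffled sequences. Against windows of the same peaks, NFY, AP-1, NF-kB, HNF4, HNF1, MEF2 and C/EBP sites passed in neither direction. Without added bases the RUNX ratio was 0.29 and the IRF ratio 0.93, and neither passed (exact test, adjusted p = 0.15 and 0.29 in the replicate with the higher value). The call of the E2A and HEB E-box ended with 10 bp added (exact test, adjusted p = 0.75), and its ratio was -0.05 in footprints found in both replicates. Against shuffled sequences GATA had 0.05 and did not pass, while MEF2 (1.84), NFY (0.66), Ikaros (0.80) and NF-kB (-0.60) passed.

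**Figure D3:**
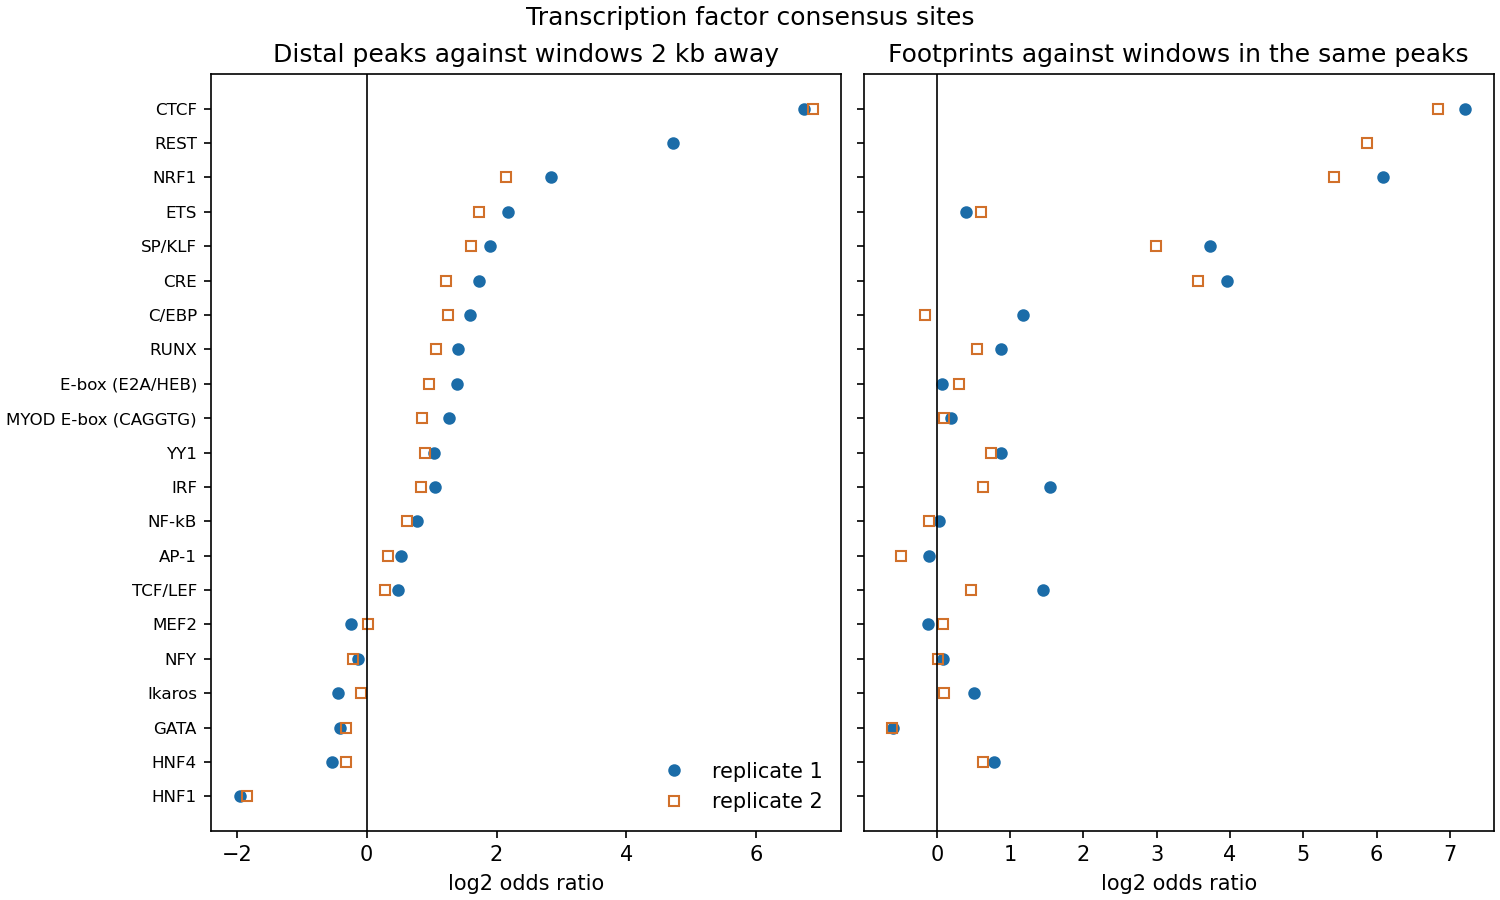
Log2 odds ratios (x axes) of 21 consensus sites (rows) in distal peaks against windows 2 kb away (left) and in footprints against windows of the same peaks (right), with filled circles for replicate 1 and open squares for replicate 2; a point is left out where either side had no site. CTCF stands at 6.80 and 7.03 as means, and ETS sites at 1.96 and 0.50.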

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

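The tests of depth, of repeated sequence among the strongest peaks and of CTCF sites against ubiquitous promoters were chosen after the result was seen; the other tests below were written down before their own result was seen, the one of GC content after the CTCF pattern was known. The CTCF pattern itself was found by comparing motifs, GC content and strength on these data. Peaks on the Y chromosome stood out because both animals are female and the gene lists were compared on chromosomes 1 to 19 and X. Replicate 1 had 59 such peaks and replicate 2 had 42, of which 27 overlapped between replicates, and their median strengths of 0.203 and 0.227 lay below the medians of all peaks (0.795 and 0.645). Reads from sequence that also lies on another chromosome are a candidate explanation. Exact copies of the sequence off the Y were found for 59.3% of the Y peaks of replicate 1 and 38.1% of those of replicate 2, a mean of 48.7%, which lies between the bounds set for and against it. Counting copies on the Y as well, 45 Y peaks of replicate 1 and 25 of replicate 2 had a median of at least 2 genome copies. The other 14 and 17 had 1 copy. On autosomes 2.05% and 1.88% of peaks had at least 2. Copies that differ by a base or come from the CAST genome were not counted. The explanation by reads from another chromosome therefore stays open, and no biological explanation was tested.

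Some of the strongest peaks lie in repeated sequence. Among the 50 strongest shared peaks 7, or 14.0% (95% Clopper-Pearson interval 5.82 to 26.7%), had a median of at least 2 genome copies of their words, against 2.00% of all shared peaks. The copies of the 5 strongest had been seen before this count, and without them 3 of 45 remained, or 6.67% (1.40 to 18.3%), an interval that holds the 2.00% of all shared peaks. Whether reads stacked on 1 copy of a repeat raise these strengths therefore stays open, and no biological explanation was tested. Copies that the assembled chromosomes lack were not counted.

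Among 47806 distal peaks that paired one to one, the 4883 with the CTCF consensus ranked higher in replicate 2, with a median strength percentile of 51.2 in replicate 1 and 76.9 in replicate 2, whereas those with ETS sites had 59.6 and 43.8, and the median log2 ratio of replicate 1 to replicate 2 was 1.06 lower with than without the consensus (difference -1.06, 95% bootstrap interval -1.07 to -1.03), which argues against a depth factor alone. Within 16 classes of GC content and mean strength the difference was -1.15 (-1.18 to -1.13), which argues against GC content as the cause. A lower share of thymocytes in replicate 2 cannot be told apart for the thymocyte genes, since the ubiquitous promoters lay -0.34 from them with an interval of -0.79 to 0.16, or -0.69 (-1.26 to -0.27) with both lists set against promoters of like strength, which does not clear the bound of -0.3 set for it. Nor can it be told apart for the gap between CTCF sites and ubiquitous promoters, where CTCF sites matched to 13 of the 15 promoters within 0.25 log2 units of mean strength lay -0.51 from them with an interval of -1.08 to -0.24, which reaches past the bound of -0.5 set against it. In width, replicate 1 minus replicate 2, the median difference of these distal pairs was 0 bp with the CTCF consensus and -34 bp without it. Differences in DNase digestion or fragment size between the libraries, which were not tested here, and a difference between the animals stay open.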

How the results depend on the processing

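The overlap with the other replicate's false discovery rate track, the CTCF difference within classes and the matching of promoters on strength were chosen after the data were examined, the CTCF difference within classes before its own value was seen; all other alternatives were fixed before. Over 87 results, 409 of 492 alternative values were classed as unchanged. Tested values in that class kept their direction and their side of the threshold, or turned direction while neither setting passed. Numbers in it stayed within a fixed ratio of the main value, and other values moved by no more than their error. Of the rest, 44 moved beyond those limits, 16 passed a threshold they had missed and 13 no longer passed. The remaining 10 turned direction with at least 1 setting past the threshold. Of the 409, 153 came from leaving out a replicate, and many of these could not have changed. A motif call already needed each replicate to pass in the same direction, so leaving out either could not undo it. For shares and numbers given as means of the replicates, either replicate lies within their SD by arithmetic. Such values do not test how far a result depends on a replicate. The thymocyte and T cell list stayed past both list tests in every alternative run, at 36.8 to 48.8 percentage points above background and 52.9 above CpG-matched lists for promoters, and at 9.54 to 16.4 distal peaks per 100 kb above random lists. Depth is not stated, so what it limits was not tested; the weakest 10% of peaks were shared in 25.1% and 13.0% of cases. No paired analysis was possible because there is 1 group.

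Shared peaks of replicates 1 and 2 were 56.8% and 51.1% with reciprocal overlap, 85.0% and 75.4% in the stronger 50% of each list (Jaccard 0.487), 73.8% and 72.4% with equal numbers (0.448), 80.3% and 70.3% at a false discovery rate of 0.001 (0.468), and 82.4% and 69.7% when any listed base counted. Spearman's rho was 0.821 with reciprocal overlap and 0.720 in the stronger 50%, and Pearson's r was 0.852. TSS-proximal, exon, intron and intergenic shares were 27.8%, 7.04%, 38.5% and 26.6% in the stronger 50%, 25.6%, 6.39%, 38.5% and 29.5% with 1000 bp windows, and 31.7%, 5.40%, 34.8% and 28.1% with 2000 bp; with TSSs of all genes the first was 21.4%, exons 6.58% and intergenic space 30.2%. Shared footprints were 33.5% with reciprocal overlap and 56.4% inside shared peaks. The CTCF difference was -1.15 within classes. The windows and overlap rules change these values by construction; for the rest below the cause was not tested.

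Against CpG-matched lists, 2 of 7 promoter calls remained in number, and the differences in percentage points were -3.90 (myeloid), -12.7 (erythroid), 12.3 (cell cycle), 13.1 (ubiquitous) and -20.4 (hepatocyte); cell cycle and ubiquitous genes, at 100%, could not pass upward there. In the stronger 50%, endothelium and mesenchyme (-31.3) and neurons (-29.9) passed; leaving out a replicate gave -28.1 to -20.4 for endothelium and mesenchyme, past the threshold without replicate 1. Distal tests called 2 lists with 100 kb flanks, in the stronger 50% and without span matching, and 2 to 3 without a replicate, against 1. The added lists were myeloid at 100 kb (difference 4.39), ubiquitous in the stronger 50% (4.70), without matching (5.41) and without a replicate (5.43 to 7.08), and B cell without replicate 1 (5.00), but not without replicate 2 (3.56).

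In footprints, shuffled controls turned the log2 odds ratios of GATA (0.053), which no longer passed, and of MEF2 (1.84), which passed. NFY (0.66), NF-kB (-0.60) and Ikaros (0.80) passed as well. Without added bases RUNX (0.29) and IRF (0.93) no longer passed. With 10 bp, E-box sites (0.093) no longer passed, Ikaros (0.30) passed and NF-kB turned (0.46). In shared footprints the E-box turned (-0.045), AP-1 passed (-0.59) and 2 motifs were depleted, against 1. Leaving out a replicate gave 1 to 2 depleted motifs, -0.49 to -0.11 for AP-1 and 0.10 to 0.50 for Ikaros. In distal peaks, shuffled controls turned GATA (0.17), NF-kB (-0.23), Ikaros (0.47), HNF1 (0.16), MEF2 (1.63) and C/EBP (-1.26). Depleted motifs fell from 5 to 3 in the stronger 50% and in shared peaks, where HNF4 (-0.55 and -0.41) and HNF1 (-1.36 and -1.31) no longer passed, nor YY1 in shared peaks (0.95).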

Other observations

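The test of antigen receptor segments was written down before its result was seen; the values by locus and the test of Igh alone, the listing of unshared peaks and the strength ratios were chosen after the result was seen. Of 226 T cell receptor segments, 80 (35.4%) overlapped a peak within 100 bp in both replicates, against 47 of 264 immunoglobulin segments (17.8%), a difference of 17.6 percentage points (Fisher's exact test, p = 1.24e-05). This difference lay with the light chains: the heavy chain locus Igh had 47 of 142 segments open (33.1%; Fisher's exact test against the T cell receptor segments, p = 0.74), and Igk and Igl had none of 106 and 12. By locus, 48 of 108 Tra V segments, 13 of 22 Trb V segments, 3 of 5 Trd V segments and 2 of 7 Trg V segments were open. Among J segments 5 of 13 at Trb and 3 of 51 at Tra were open, and none of 2 at Trd or 4 at Trg. Both C segments at Trb and the 1 at Trd were open, but not the 1 at Tra or the 4 at Trg. At Igh 41 of 113 V, 2 of 17 D, 2 of 4 J and 2 of 8 C segments were open. Other differences between loci were not tested, and V segments of a family resemble each other in sequence.

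Peaks without a partner were mostly not listed at all in the other animal. Of the 24033 unshared peaks of replicate 1, 29.04% held a base under a false discovery rate of 0.05 in replicate 2, and of the 36322 unshared peaks of replicate 2, 9.99% did so in replicate 1. A further count placed a peak of the other replicate within 150 bp of 16.5% and 11.4% of them. Unshared peaks were weak, with median strengths of 0.400 and 0.328 against 1.07 and 1.03 for shared peaks.

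Promoters of the thymocyte and T cell list ranked relatively higher in replicate 1. The median log2 ratio of promoter strength, replicate 1 over replicate 2, was 1.35 for its 40 genes and 0.64 for the 12606 open promoters outside the lists, with 0.99 for cell cycle genes, 1.01 for ubiquitous genes, 0.48 for thymic epithelial genes and 0.20 for endothelial and mesenchymal genes. These medians are not matched on strength, and over all paired peaks the ratio was 0.12 in the weakest 25% by mean strength and 0.77 in the strongest 25%. Set against promoters outside the lists within 0.25 log2 units of the same mean strength, the thymocyte and T cell list stood 0.64 higher (95% bootstrap interval 0.43 to 0.86), against 0.71 (0.45 to 0.84) unmatched, and cell cycle genes 0.25 (0.13 to 0.33), against 0.35 (0.16 to 0.56). Matching changed the other lists more. Effector lymphocyte genes stood at 0.53 (0.15 to 0.57) matched but at 0.03 (-0.28 to 0.71) unmatched, and ubiquitous genes at -0.06 (-0.51 to 0.33) against 0.37 (-0.05 to 0.79). The other 4 lists with at least 5 such promoters turned from negative to positive differences, with intervals that held 0 both ways. Unmatched, the ubiquitous genes lay -0.34 from the thymocyte and T cell list, with an interval of -0.79 to 0.16 that holds 0. Only differences between these medians carry information, since the scale of each replicate is not stated. Among distal peaks, REST sites, like CTCF sites, had a ratio below that of other peaks (-0.55 for 68 peaks against 0.13), as had Ikaros (-0.04), HNF4 (-0.01) and HNF1 (-0.07, 3 peaks) sites. The other 16 of the 21 motifs lay above the peaks without them, from YY1 (0.16) to ETS (0.65), RUNX (0.67) and CRE (0.71). Within classes of GC content and strength, where 19 motifs had a value, CTCF (-1.15), REST (-0.75) and Ikaros (-0.14) stayed below and HNF4 turned (0.10).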
